A study of Caenorhabditis elegans with 26 samples.

How the data were processed

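Expression was measured in Caenorhabditis elegans embryos on 26 Affymetrix expression arrays, hybridised with biotin-labelled cRNA made from total RNA. The labels and the series text place the arrays in 6 groups. Embryos with the genotype her-1; xol-1 sdc-2(y74) unc-9 and 1 X chromosome (XO, strain TY2222, 8 arrays) have wild-type XX controls from egg plates (6 arrays). Embryos made sdc-2 mutant by the y93 allele together with feeding RNAi (3 arrays) have wild-type XX controls fed bacteria with an empty plasmid (3 arrays). Embryos with dpy-27(y57) (3 arrays) have wild-type XX controls from NG plates (3 arrays). The series text calls the replicates biological, and each array has its own column of values. The sample titles carry a date, written here as date codes 1 to 5 in calendar order.

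The deposited values are log2 expression values per probe set, made with RMA per the submitters' processing notes, whose version is not given in the sources used here. They run from 3.07 to 14.5 over 22548 probe sets. Quartiles were nearly equal among the arrays of a plate type and differed between plate types. The standard deviation over probe sets was 2.00 to 2.06 on RNAi plates, 2.27 to 2.32 on egg plates and 2.41 to 2.45 on NG plates, so the 3 plate types appear to have been normalised apart. Mutants were therefore compared only with controls of their own plate type. The planned test of wild-type embryos from NG plates against those from egg plates over all genes was not run for that reason. After joint quantile normalisation, levels of heat-shock genes alone were set side by side across plate types. Arrays give no read depth, and the number of arrays limits the precision.

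Probe sets were assigned to genes with the array annotation, and chromosomes came from the NCBI gene table by gene ID. Of the probe sets, 20766 name 1 gene and were kept, 887 name several genes and 895 have no gene listed. For the 2981 genes with several probe sets, the probe set with the highest mean over all 26 arrays was kept. This gave 17118 genes, of which 2352 are X-linked, 14721 autosomal and 8 mitochondrial, and 37 have no chromosome in the table. The kept probe set of 4236 genes ends in _s_at or _x_at, which marks probes that can match several transcripts, so the values of those genes are less certain. No filter on low values was used in the tests of genes.

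Differences were tested with limma version 3.58.1 in R version 4.3.3. A single model with a mean for each group was fitted to all 26 arrays, with 20 residual and 3.21 prior degrees of freedom. Genes count as changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over the 17118 genes of a comparison. Each log2 change of a gene is given with its standard error (SE) from this fit. The fit has no date term, so its spread includes date differences within the egg-plate groups. For sdc-2 and dpy-27 embryos the SEs and calls therefore do not reflect the scatter of their own arrays alone. SEs of X shifts come from the compared arrays alone. Differences between the effects of 2 genotypes were tested as differences within the same model. They set changes from plate types that appear to have been normalised apart against each other, which limits them. The shift of the X chromosome was computed per array. It is the median over expressed X-linked genes, minus the median over expressed autosomal genes, of the log2 value less the gene's mean in the control arrays. Expressed genes are the 8559 with a mean above 6.4 over all arrays (1267 X-linked, 7267 autosomal). Group means of that value were compared with a two-sided exact permutation test, for which 3 against 3 arrays cannot give a p below 0.1. Differences of 2 such shifts were tested by an exact permutation of the labels within each comparison, which assumes no shift in either. Date differences were tested in a limma fit with a mean for each group and date code on the egg-plate arrays.

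Lists of genes, 22 in all, were tested in the 3 comparisons (66 tests) with limma's camera at a preset correlation of 0.01, and again with a correlation estimated from the arrays. Benjamini-Hochberg adjustment ran over the 66 tests. The function fry tested whether the genes of a list moved, on balance, 1 way. The lists cover the dosage compensation complex, sex determination and X counting, early maternal messages, early zygotic regulators, body wall muscle, pharynx, neurons, intestine, epidermis and cuticle, yolk and adult body, sperm, germline, cell division and chromosome segregation, chromatin and synMuv genes, heat shock and unfolded protein, detoxification and oxidative stress, innate immunity, RNA interference machinery, fatty acid and glyoxylate metabolism, oxidative phosphorylation, ribosomal proteins and programmed cell death.

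The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 5 genes named in the genotypes. It adds the 8 largest rises, the 8 largest falls, the 6 largest X-linked rises and the 4 largest X-linked falls that passed the threshold, had no overlap between the groups' arrays, a gene name of letters and a number, and a probe set not ending in _s_at or _x_at. It also takes up to 4 members of each list, by smallest p. For differences between effects and between dates it takes the 4 largest each way. Not every gene the rule allows is named in the text.

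Alternatives were re-centring of each array on its autosomal median, quantile normalisation, a filter on dim genes, fits to the compared groups alone, an intensity trend with a robust prior, array weights, other choices of probe set, stricter thresholds, the date code as a random or fixed block, the replicate letter as a block, only the shared date code, and leaving out each array in turn. The random block of date codes spans plate types that appear to have been normalised apart, which limits it. Some alternatives for the differences between effects, the date differences, the lists in XO embryos and the correlations were added after seeing the data.

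The pipeline was tested on simulated data with 200 changed genes per comparison among 17118. At 2-fold, 95.5% of the changed genes were recovered for the XO comparison, 83.6% for sdc-2 and 80.6% for dpy-27. At 1.5-fold these shares were 82.1%, 49.3% and 46.3%, and 4.2%, 3.2% and 4.5% of the calls were false. The simulated noise was independent between genes and arrays and held no date difference. These shares therefore do not cover calls that a difference between date codes would make. An X shift of 0.5 added to simulated arrays was found as 0.499, 0.501 and 0.493.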

Results

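Embryos from bleached adults were profiled on 26 arrays, 1 per biological replicate. Each mutant genotype has wild-type XX controls grown on the same plate type. The study asks how the dosage compensation complex acts on expression. In C. elegans this complex binds both X chromosomes of XX embryos and lowers their output. SDC-2 brings the complex to X, and DPY-27 is one of its condensin-like subunits. XO embryos normally lack an active complex. Arrays of the same group and date code correlated with each other over genes at 0.984 to 0.999. Date code and genotype coincide in the sdc-2 comparison (codes 5 and 3) and in the dpy-27 comparison (codes 1 and 2). In the XO comparison date code 2 holds both groups, with 3 arrays each.

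X-linked genes rose in sdc-2 XX embryos while many autosomal genes fell. Of 2352 X-linked genes, 722 rose and 15 fell, and of 14721 autosomal genes 689 rose and 1956 fell. X-linked genes made up 51% of the rises and 13.7% of the genes tested. The male-determining signal her-1, which SDC-2 represses in XX embryos, rose 6.34-fold (log2 2.66, SE 0.11, 3 against 3 arrays). The X-linked switch gene xol-1, which sets male fate, rose 3.94-fold (log2 1.98, SE 0.34) on its brighter probe set and by 0.48 (adjusted p = 0.0256) on the other.

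Relative to autosomes, expressed X-linked genes stood 1.59-fold higher in sdc-2 embryos than in their controls (log2 0.67, SE 0.06, 3 against 3 arrays). The 3 mutant arrays lay between 0.60 and 0.76 and the 3 controls between -0.05 and 0.07, and the two-sided exact permutation p was 0.1, the smallest that this design allows. The median change was 0.47 over expressed X-linked genes and -0.19 over expressed autosomal genes. Each autosome had a median below 0, from -0.23 on chromosome III to -0.15 on chromosome IV. Over all genes, dim ones included, the X shift was 0.295.

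**Figure D1:**
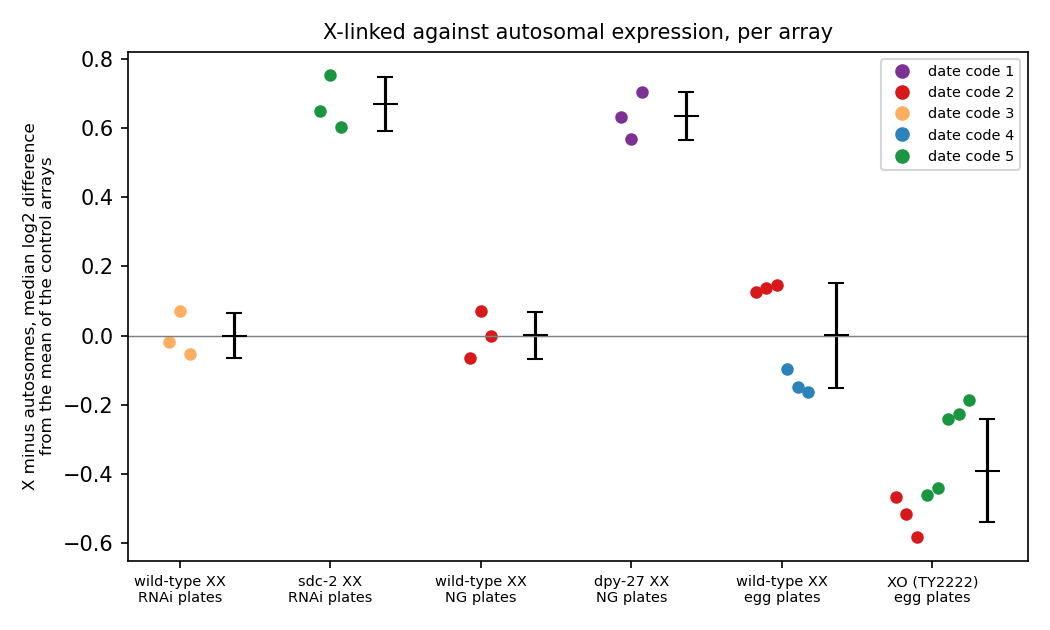
Each point is the median log2 difference of expressed X-linked genes minus that of expressed autosomal genes in 1 array, against the mean of its control arrays, coloured by date code, with group means and standard deviations beside the points. The sdc-2 and dpy-27 arrays average 0.67 and 0.64, and the XO arrays average -0.39.

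Of the genes named in the genotypes, sdc-2 itself gave -0.36 (SE 0.17, adjusted p = 0.158) on its brighter probe set in sdc-2 embryos, and the other probe set fell by 1.37 (adjusted p = 5.2e-05). The dpy-27 transcript fell by 0.57 (SE 0.16) on its brighter probe set and gave 0.30 (adjusted p = 0.301) on the other, and the call was lost with re-centring (-0.50) and with the mean of probe sets (-0.13). The innexin gene unc-9, which is X-linked, rose by 1.67 (SE 0.52), and its other probe set gave 0.92 (adjusted p = 0.102); the call was lost without any 1 of 4 of the 6 arrays. Among the largest X-linked rises that the naming rule admits were the non-coding RNA gene tts-1 (log2 3.33, SE 0.45), the immunoglobulin gene zig-3 (2.64, SE 0.14), the metalloprotease gene nas-38 (2.60, SE 0.36), dbd-20 (2.57, SE 0.66), the branched-chain aminotransferase gene bcat-1 (2.17, SE 0.20) and the histone demethylase gene jmjd-3.3 (2.05, SE 0.29). The largest X-linked falls it admits were in the collagen receptor gene ddr-1 (-1.11, SE 0.23), the collagen gene col-172 (-0.96, SE 0.26), vhl-1 (-0.76, SE 0.22) and nnt-1 (-0.71, SE 0.17).

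Of the autosomal genes of sdc-2 embryos that the naming rule admits as largest rises, with probe sets not ending in _s_at or _x_at, dbd-13 (log2 4.47, SE 1.00), the cystatin gene cpi-1 (4.11, SE 0.77), grl-21 (3.87, SE 0.54), srlf-34 (10.5-fold, log2 SE 0.46), the antimicrobial peptide gene cnc-4 (3.02, SE 0.38) and the phospholipase gene ipla-7 (2.68, SE 0.62) rose most. Between date codes 2 and 4 of the wild-type egg-plate embryos, dbd-13 and cpi-1 also differed, by 3.81 and 3.55. The largest falls it admits were in the autophagy gene atg-9 (-2.23, SE 0.52), the flavin monooxygenase gene fmo-2 (-1.97, SE 0.34), the cap-binding protein gene ncbp-2 (-1.92, SE 0.38), the alcohol dehydrogenase gene adh-1 (-1.89, SE 0.48), the nuclear anchorage gene anc-1 (-1.78, SE 0.25), ech-4 (-1.72, SE 0.21), rhgf-3 (-1.66, SE 0.21) and the copper chaperone gene cox-17 (-1.64, SE 0.33). Between date codes 2 and 5 of the XO embryos, atg-9 differed by 1.96.

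**Figure D2:**
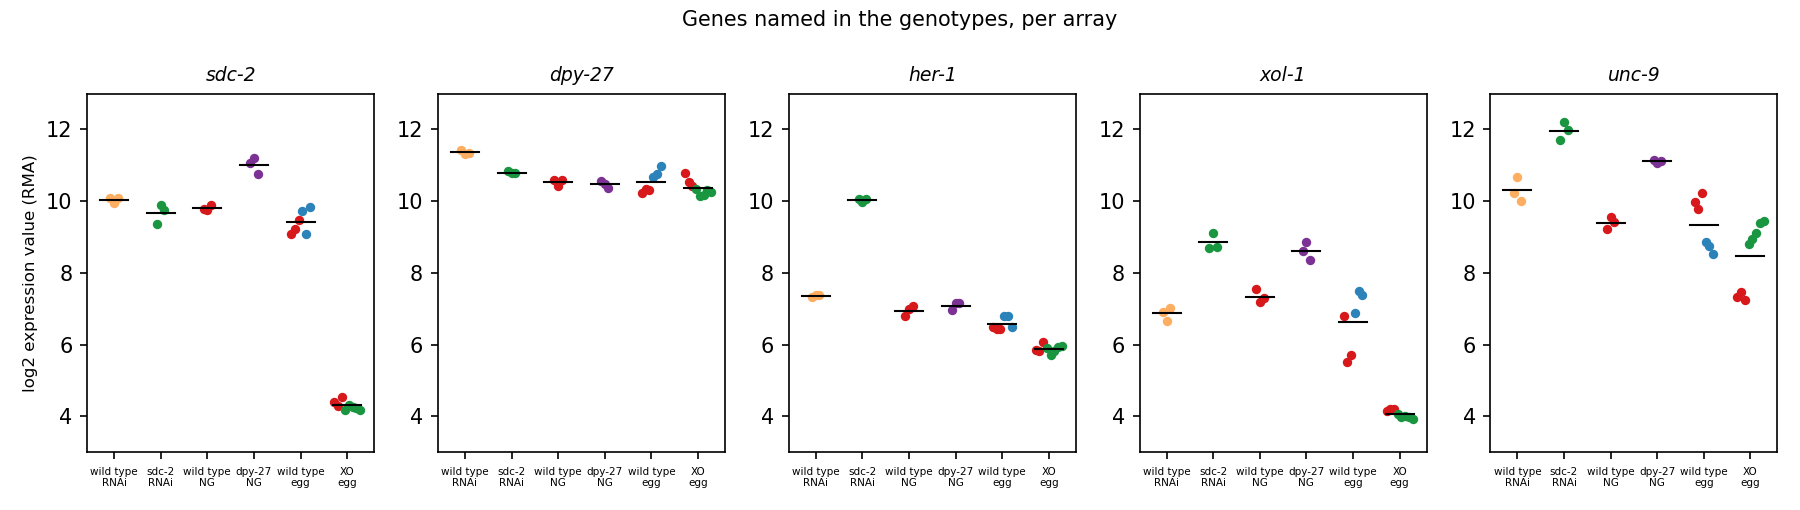
Points are log2 expression values of the genes named in the genotypes, 1 per array and coloured by date code as in the plot of X minus autosomes, and bars are group means. The sdc-2 values average 4.31 in XO embryos and 9.40 in their controls, and her-1 averages 10.0 in sdc-2 embryos and 7.37 in theirs.

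Sex determination and X counting genes rose as a list in sdc-2 embryos, 7 of 18, and 8 when adjusted over the list alone (camera adjusted p = 2.91e-05, adjusted p = 0.246 with an estimated correlation). Besides her-1 and xol-1 they include the X signal genes ceh-39 (log2 1.32, SE 0.24) and fox-1 (1.15, SE 0.21), both X-linked. Early maternal messages rose in 7 of 26, the same count over the list alone (adjusted p = 0.0116, adjusted p = 0.748 with an estimated correlation), among them the RNA-binding protein genes spn-4 (0.95, SE 0.20), mex-5 (0.98, SE 0.24) and mex-6 (1.05, SE 0.24). Without probe sets ending in _s_at or _x_at, mex-5 gave 0.60 (adjusted p = 0.275). Innate immunity genes rose in 6 of 26, the same count over the list alone (adjusted p = 0.0251, adjusted p = 0.697 with an estimated correlation), with nlp-29 (3.00, SE 0.33), cnc-4, and the lysozyme genes lys-1 (1.73, SE 0.50) and lys-7 (at least 0.89, SE 0.12, from a control level of 5.41 below the lower quartile of each array). Programmed cell death genes rose in 4 of 16 and fell in 2, and 7 rose and 2 fell when adjusted over the list alone (adjusted p = 0.0413, adjusted p = 0.697 with an estimated correlation). They include the death activator egl-1 (0.86, SE 0.23) and the engulfment gene ced-2 (0.67, SE 0.12).

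Ribosomal protein genes fell in sdc-2 embryos, 41 of 75, and 49 when adjusted over the list alone (adjusted p = 1.71e-14, adjusted p = 0.246 with an estimated correlation), with rps-27A at -0.78 (SE 0.12) and rpl-28 at -0.67 (SE 0.12). With each array re-centred on its autosomal median, 24 of them fell. Oxidative phosphorylation genes fell in 11 of 27 and rose in 2, and 14 fell and 3 rose when adjusted over the list alone (adjusted p = 0.0014, adjusted p = 0.701 with an estimated correlation). The cytochrome oxidase genes cox-5A (-0.69, SE 0.17) and cox-6C (-1.05, SE 0.27) fell, and sdha-1, which is X-linked, rose by 0.88 (SE 0.16).

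The remaining lists were not called by camera in sdc-2 embryos (adjusted p from 0.0546 to 0.952). Detoxification genes came nearest, with 8 of 23 fallen, among them ctl-2 (-1.54), gst-10 (-1.41) and cyp-35A3 (-1.37). Heat-shock genes fell in 3 of 18, namely hsp-1 (-0.99), crt-1 (-0.81) and hsp-60 (-0.81). The function fry called both of these lists downward (fry adjusted p = 6.52e-06 for detoxification and 0.00242 for heat-shock genes). Of 10 dosage compensation genes 3 rose, dpy-21, dpy-28 and capg-1, and 2 fell. Without probe sets ending in _s_at or _x_at the call of dpy-21 was lost. Body wall muscle genes rose in 6 of 32, with the X-linked troponin genes tnt-2 (0.96) and tnt-3 (0.84), and fell in 4, with the regulator hlh-1 (-0.98). Neuronal genes rose in 2 of 34, the X-linked unc-18 (1.34) and aex-3 (1.16), and fell in 3, with mec-12 (-1.39). Epidermal genes rose in 3 of 33, with the X-linked nhr-25 (1.16) and ajm-1 (0.99), and fell in 8, with the collagen gene dpy-2 (-0.84), and ajm-1 gave 0.17 (adjusted p = 0.606) without probe sets ending in _s_at or _x_at. Fatty acid genes rose in 3 of 26 and fell in 4, lbp-5 (-1.63), ech-6 (-1.63) and the thiolase gene daf-22 (-1.22) among the falls.

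For the other lists in sdc-2 embryos, 4 of 24 germline genes rose and 2 fell, 5 of 36 cell division genes rose and 5 fell, 4 of 22 chromatin genes rose and 8 fell, and 3 of 25 RNA interference genes rose and 1 fell. With re-centring on autosomal medians, 4 chromatin genes rose and 2 fell, and 5 cell division genes rose and 2 fell. In the intestine list 1 of 16 rose and 2 fell, in the early zygotic list 1 of 21 rose and 1 fell, and 1 fell in each of the pharynx (of 13), yolk (of 8) and sperm (of 20) lists. Adjusted over the list alone, 3 dosage compensation genes fell, 7 muscle genes rose and 5 fell, 4 epidermal genes rose and 10 fell, 5 germline genes rose, 6 cell division genes fell, 9 chromatin genes fell, 7 fatty acid genes fell and 2 neuronal genes fell. The pharyngeal fall and the zygotic fall were not called over their lists alone, and the other counts of uncalled lists stayed as given.

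In total, 3390 genes changed in sdc-2 embryos, 1417 up and 1973 down. With each array re-centred on its autosomal median, 1697 rose and 1372 fell. The count was 2089 without sdc2_XX replicate B, 2203 without WT_XX_RNAi replicate C, 5588 with array weights and 1859 at an adjusted p under 0.01. Genotype and date code cannot be told apart here, and with the date code as a random block 43 genes changed, her-1, zig-3, bcat-1, jmjd-3.3, cnc-4, nlp-29, fmo-2 and lbp-5 among them, while the other genes said above to have risen or fallen in sdc-2 embryos lost the call. Leaving out 1 array, for at least 1 choice of it, lost the calls of aex-3, capg-1, col-172, dpy-27, dpy-28, egl-1, hsp-60, lys-1, unc-9 and vhl-1. The mean of probe sets lost those of aex-3, ajm-1, capg-1, ced-2, dpy-27 and mex-5.

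X-linked genes also rose in dpy-27 XX embryos. Of 2352 X-linked genes 923 rose and 91 fell, and of 14721 autosomal genes 1981 rose and 2215 fell. X-linked genes made up 31.7% of the rises. With each array re-centred on its autosomal median, 3907 genes rose, 1101 of them X-linked, and 1654 fell, 61 of them X-linked. Rises outside X then outnumbered falls, so the autosomal balance depends on the normalisation. The largest rises that the naming rule admits were X-linked apart from cpi-1: the corepressor gene ctbp-1 rose 6.25-fold (log2 2.64, SE 0.38, 3 against 3 arrays). Over the alternatives its log2 change ran from 0.712 to 2.747, called in each. Small heat-shock and collagen genes were among the largest falls, with col-48 23.2-fold lower (log2 -4.54, SE 0.64) and hsp-16.2 21.2-fold lower (log2 -4.41, SE 0.59).

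Expressed X-linked genes stood 1.55-fold higher relative to autosomes in dpy-27 embryos than in their controls (log2 0.63, SE 0.06, 3 against 3 arrays). Mutant arrays lay between 0.57 and 0.71 and controls between -0.07 and 0.07, with a two-sided exact permutation p of 0.1, the smallest possible. The medians over expressed genes were 0.55 on X and -0.07 on autosomes. Chromosomes I to V had medians from -0.13 (II) to -0.01 (IV). Re-centring on autosomal medians raises the median of all genes by 0.102. That exceeds the size of the autosomal median of -0.07, whose sign therefore depends on the normalisation. The X shift over all genes was 0.257.

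**Figure D3:**
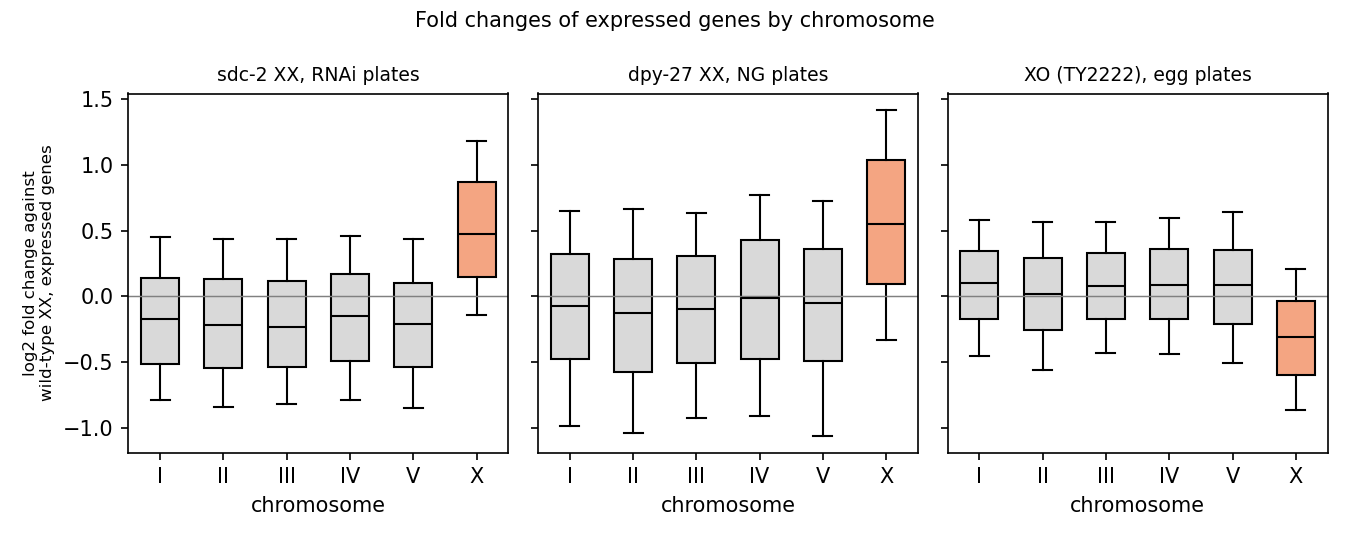
Boxes span the quartiles and whiskers the outer deciles of log2 changes of expressed genes on each chromosome, with the median as a line. The X medians are 0.47 in sdc-2, 0.55 in dpy-27 and -0.31 in XO embryos.

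Further large X-linked rises in dpy-27 embryos were in pqn-62 (log2 2.44, SE 0.43), the kinase gene jkk-1 (2.36, SE 0.32), cab-1 (2.30, SE 0.34), rig-3 (2.16, SE 0.35), the potassium channel gene twk-18 (2.12, SE 0.33) and the tetraspanin gene tsp-16 (2.06, SE 0.14). The X-linked genes with the largest falls under the naming rule were col-165 (-2.04, SE 0.37), toca-1 (-1.89, SE 0.28), col-172 (-1.34, SE 0.26) and the autophagy gene atg-2 (-1.18, SE 0.17). Transcripts of sdc-2 rose by 1.19 (SE 0.17), of xol-1 by 1.27 (SE 0.34) and of unc-9 by 1.71 (SE 0.52), all X-linked. On their other probe sets sdc-2 rose by 0.81 and xol-1 by 0.57. The other unc-9 probe set gave -0.07 (adjusted p = 0.918), and the call of unc-9 was lost with the mean of probe sets (0.82) and without WT_XX_NG replicate A. On the brighter unc-9 probe set the SD was 0.04 in dpy-27 arrays and 0.16 in their controls. It was 0.96 in XO arrays and 0.72 in egg-plate controls, which share the pooled spread behind the SE of 0.52. The autosomal her-1 gave 0.14 (SE 0.11, adjusted p = 0.369). The dpy-27 transcript itself gave -0.05 (SE 0.16, adjusted p = 0.842) on its brighter probe set and rose by 0.81 (adjusted p = 0.00174) on the other, so the transcript level does not mark the mutant genotype.

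Among autosomal genes of dpy-27 embryos, cpi-1 rose by 2.06 (SE 0.77, adjusted p = 0.0441), a call that was lost whichever of the 6 arrays was left out. After col-48 and hsp-16.2, the largest falls under the naming rule were in hsp-16.41 (-4.04, SE 0.54), col-77 (-3.44, SE 0.62), the exoribonuclease gene xrn-2 (-3.26, SE 0.46), mcd-1 (-3.17, SE 0.50), lido-9 (-2.77, SE 0.50) and pqn-41 (-2.72, SE 0.28). Over the alternatives pqn-41 ran from -2.795 to -0.799, called in each. The genes mcd-1, lido-9 and xrn-2 were also higher at date code 2 than at date code 5 in XO embryos, by 2.01, 1.85 and 1.82, and date code 2 is that of the controls here.

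Heat-shock and unfolded protein genes fell in dpy-27 embryos, 10 of 18, and 12 when adjusted over the list alone (adjusted p = 7.66e-07, adjusted p = 0.00186 with an estimated correlation). They include the mitochondrial chaperone gene hsp-60 (-2.47, SE 0.23) and the cytosolic chaperone gene hsp-1 (-1.87, SE 0.19). Detoxification and oxidative stress genes fell in 12 of 23, the same count over the list alone (adjusted p = 2.13e-06, adjusted p = 0.00089 with an estimated correlation), with the metallothionein gene mtl-2 (-1.20, SE 0.13), the cytochrome P450 gene cyp-35A3 (-1.63, SE 0.18), the superoxide dismutase gene sod-1 (-1.55, SE 0.18) and the glutathione transferase gene gst-5 (-1.33, SE 0.21). These were the calls, of 19 in all comparisons, that held with an estimated correlation.

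Oxidative phosphorylation genes fell in 20 of 27 and rose in 2 in dpy-27 embryos, the same counts over the list alone (adjusted p = 2.81e-09, adjusted p = 0.246 with an estimated correlation), with the ATP synthase genes atp-3 (-1.20, SE 0.13) and atp-2 (-0.73, SE 0.09) and with cox-5A (-1.47, SE 0.17). Ribosomal protein genes fell in 48 of 75 and rose in 3, and 51 fell when adjusted over the list alone (adjusted p = 4.35e-16, adjusted p = 0.246 with an estimated correlation), with rpl-13 at -1.27 (SE 0.13) and rps-9 at -1.17 (SE 0.11). With each array re-centred on its autosomal median, 29 of them fell and 3 rose. Early maternal messages fell in 9 of 26 and rose in 1, and 10 fell when adjusted over the list alone (adjusted p = 0.00221, adjusted p = 0.701 with an estimated correlation). The eggshell receptor gene egg-1 (-0.99, SE 0.16), the Y-box gene cey-2 (-1.01, SE 0.18) and oma-2 (-1.28, SE 0.24) fell, and oma-2 gave 0.30 (adjusted p = 0.381) on the probe set used when those ending in _s_at or _x_at were left out.

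The other lists were not called by camera in dpy-27 embryos (adjusted p from 0.089 to 0.967). Of these, fry called cell death (fry adjusted p = 0.0132) and dosage compensation genes (0.0294) upward. It called yolk and adult (0.0137), fatty acid (0.0294) and epidermal genes (0.0309) downward. Epidermal genes rose in 10 of 33 and fell in 15. The collagen genes dpy-13 (-2.12), dpy-17 (-1.98) and sqt-3 (-1.48) fell and the X-linked junction gene ajm-1 (1.07) rose, but sqt-3 gave 0.20 and ajm-1 -0.15 without probe sets ending in _s_at or _x_at. Muscle genes rose in 11 of 32, with the X-linked tnt-3 (1.27) and unc-97 (1.24), and fell in 9, with pat-4 (-1.07). Intestinal genes rose in 2 of 16, with the X-linked GATA factor gene elt-2 (1.44), and fell in 5, with the protease gene asp-1 (-2.08). Germline genes rose in 4 of 24, with mes-3 (0.81) and fbf-2 (0.66), and fell in 6, with the P granule gene pgl-1 (-1.90). Fatty acid genes rose in 3 of 26 and fell in 6, with ech-6 (-2.01), the glyoxylate enzyme gene icl-1 (-1.51) and daf-22 (-1.40). Neuronal genes rose in 4 of 34, with aex-3 (1.85) and unc-18 (1.09), and fell in 3. Of 16 cell death genes 7 rose, with egl-1 (1.03) and ced-8 (0.89), and 2 fell.

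The dosage compensation list had 4 of 10 genes risen in dpy-27 embryos, with sdc-2, capg-1 (0.69) and dpy-28 (0.67), and the sex determination list 5 of 18, with fem-1 (0.74), xol-1 and ceh-39 (0.87). With the mean of probe sets fem-1 gave 0.17 and ceh-39 0.11, and the calls of these genes and of capg-1, fbf-2 and oma-2 in dpy-27 embryos were lost. The innate immunity list had 2 of 26 risen and 4 fallen, with cnc-4 at -1.82. For cell division genes 8 of 36 rose and 4 fell, for chromatin genes 7 of 22 rose and 6 fell, for RNA interference genes 6 of 25 rose and 4 fell, and for early zygotic regulators 4 of 21 rose and 1 fell. The pharynx list had 2 of 13 risen and 1 fallen, 3 of 8 yolk and adult genes fell and 1 of 20 sperm genes fell. Adjusted over the list alone, 11 epidermal genes rose and 17 fell, 12 muscle, 3 intestinal, 6 germline, 9 cell division and 8 cell death genes rose, 8 chromatin genes rose and 8 fell, and 7 RNA interference and 7 fatty acid genes fell. The fall in the sperm list was then not called, and the other counts of uncalled lists stayed as given.

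In dpy-27 embryos 5228 genes changed, 2916 up and 2312 down, against 3907 up and 1654 down with each array re-centred on its autosomal median, which moves the median of all genes by 0.102. At an adjusted p under 0.01 the count was 3438, and with at least 1.5-fold change 3425. Genotype and date code cannot be told apart in this comparison either, and 1063 genes changed with the date code as a random block. In that fit the genes xol-1, unc-9, cnc-4, col-172, egl-1, dpy-28, ceh-39, capg-1, ced-8, unc-18, egg-1 and fbf-2 lost their calls in dpy-27 embryos.

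Many X-linked genes rose in both sdc-2 and dpy-27 embryos, 529, against 283.3 if the calls were independent, and 497 against 344.1 among genes above the median level. On autosomes 367 genes rose in both (92.7 if independent) and 886 fell in both (294.3 if independent). Across genes, which are not independent replicates, the log2 changes of the 2 genotypes correlated at r = 0.633 over expressed X-linked genes and r = 0.530 over expressed autosomal genes (Spearman 0.663 and 0.550). The X shifts differed by 0.04 (SE 0.08, 3 arrays a group), and leaving out 1 array gave differences from -0.01 to 0.07.

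Single genes did differ between the effects of sdc-2 and dpy-27: 1526 in all, 553 higher and 973 lower in sdc-2. These differences span plate types that appear to have been normalised apart, and after joint quantile normalisation 611 were higher and 763 lower. The effect on her-1 was 2.53 higher (SE 0.15), and that on sdc-2 transcripts 1.55 lower (log2 -1.55, SE 0.24), in sdc-2 embryos. The effects on cnc-4 (4.83, SE 0.54), hsp-16.2 (4.08, SE 0.83), hsp-16.41 (4.06, SE 0.76) and col-48 (3.31, SE 0.90) were higher in sdc-2, and those on rhgf-3 (-2.06, SE 0.30), the nuclear receptor gene nhr-163 (-1.92, SE 0.25) and pptr-1 (-1.91, SE 0.31) lower. The count fell to 993 without dpy27_XX replicate C and to 1010 without WT_XX_RNAi replicate B.

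**Figure D4:**
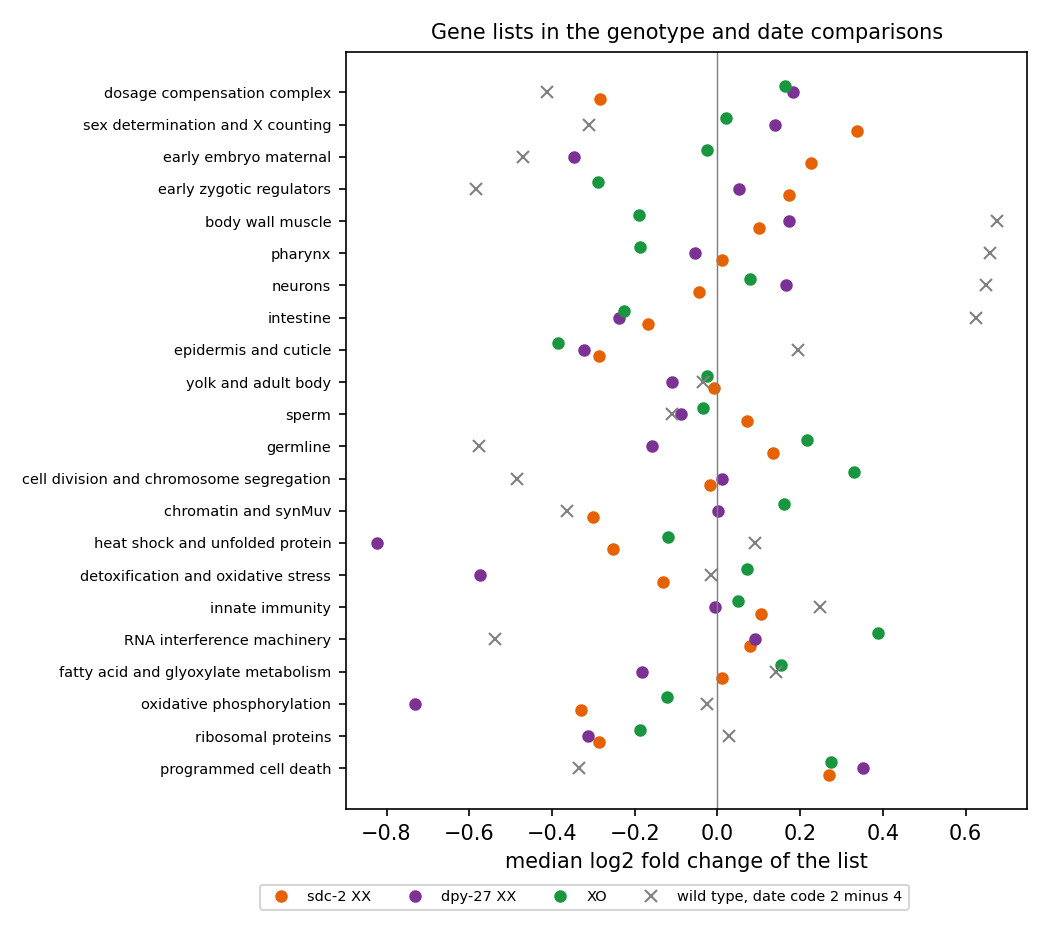
Points are the median log2 change of each gene list in the 3 genotype comparisons, and crosses the median difference between date codes 2 and 4 of wild-type embryos. Heat-shock genes have a median of -0.82 in dpy-27 embryos, and muscle genes a median of 0.67 between the wild-type dates.

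In XO embryos X-linked genes fell relative to wild-type XX embryos, the comparison of a single X without the complex to a pair of X chromosomes with it. Of 2352 X-linked genes 785 fell and 63 rose, and of 14721 autosomal genes 1623 fell and 2624 rose. X-linked genes made up 32.6% of the falls. The largest fall was in sdc-2, mutated in this strain, at least 34.3-fold lower (log2 -5.10, SE 0.11, 8 against 6 arrays, 4.31 ± 0.12 against 9.40 ± 0.33, SD). Its other probe set fell by 4.62. Of the other mutated genes xol-1 fell by 2.56 (SE 0.23) on 1 probe set and by 0.71 on the other, her-1 fell by 0.69 (SE 0.07), and unc-9 gave -0.88 (SE 0.35, adjusted p = 0.0582) on its brighter probe set and fell by 1.27 (adjusted p = 0.000531) on the other. The XO levels of sdc-2 (4.31) and xol-1 (4.07) lie below the lower quartile of each egg-plate array (4.86 to 4.95), where background limits the signal, so these falls are lower bounds.

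Relative to autosomes, expressed X-linked genes stood at 0.762 of their level in wild-type XX embryos (log2 -0.39, SE 0.08, 8 against 6 arrays, two-sided exact permutation p = 0.000999 over 3003 splits). No XO array overlapped the controls, and the nearest lay at -0.19 (XO) and -0.16 (wild type). The SE and this permutation treat all arrays as independent, although arrays of a date code lay together. They can therefore overstate the precision. The median change was -0.31 on X and 0.08 on autosomes. Over all genes the X shift was -0.17. Within date code 2, with 3 arrays a group, the shift was -0.676 (exact permutation p = 0.1, the smallest possible). By date code the XO arrays averaged -0.52 (code 2) and -0.31 (code 5), and the wild-type arrays 0.14 (code 2) and -0.14 (code 4).

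Among genes that the naming rule admits, the largest rises in XO embryos were in the cystathionine synthase gene cbs-2 (log2 2.60, SE 0.18), the glucuronosyltransferase gene ugt-31 (2.48, SE 0.42), the glycerol-phosphate dehydrogenase gene gpdh-1 (2.26, SE 0.28), the neuropeptide gene nlp-55 (2.25, SE 0.23), srlf-24 (2.09, SE 0.12), the eggshell gene perm-1 (2.02, SE 0.11), the fatty acid desaturase gene fat-7 (at least 1.98, SE 0.46, from a control level of 4.58 at background) and pll-1 (1.79, SE 0.16). The largest falls it admits besides sdc-2 were in txdc-12.2 (-2.11, SE 0.23) and fbxb-71 (-1.53, SE 0.17) on X and in sdz-30 (-1.89, SE 0.26), skr-10 (-1.56, SE 0.20), the acyl-CoA dehydrogenase gene acdh-1 (-1.51, SE 0.39), anc-1 (-1.51, SE 0.17) and fbxb-10 (-1.49, SE 0.25) on autosomes. Over the alternatives anc-1 ran from -1.622 to -0.36, called in each. On X, the transcription factor gene hnd-1 fell by 1.41 (SE 0.14), and jmjd-3.3 (1.16, SE 0.19) and the receptor gene srd-48 (0.22, SE 0.06) rose. A fixed block of date codes takes the genotype effect from date code 2 alone, since codes 4 and 5 each hold a single egg-plate group. With the date code as a fixed block the calls of ugt-31 (1.31, adjusted p = 0.119), fat-7 (1.04, adjusted p = 0.304), fbxb-10 (-0.29, adjusted p = 0.148) and srd-48 (0.16, adjusted p = 0.183) were lost. In that fit unc-9 fell by 2.64 (adjusted p = 1.47e-08), and dpy-27, at -0.18 in the joint fit (adjusted p = 0.226), rose by 0.29 (adjusted p = 0.0317).

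Cell division genes rose in XO embryos, 18 of 36, and 19 when adjusted over the list alone (adjusted p = 8.11e-07, adjusted p = 0.697 with an estimated correlation), with the mitotic kinase genes cdk-1 (0.91, SE 0.08) and plk-1 (0.76, SE 0.07) and the kinetochore gene knl-1 (0.85, SE 0.10). RNA interference genes rose in 14 of 25 and fell in 1, and 16 rose when adjusted over the list alone (adjusted p = 2.95e-05, adjusted p = 0.619 with an estimated correlation), with mut-15 (1.27, SE 0.11), rrf-3 (0.75, SE 0.12) and drh-3 (0.48, SE 0.07). Germline genes rose in 11 of 24 and fell in 1, the same counts over the list alone (adjusted p = 0.00437, adjusted p = 0.748 with an estimated correlation), with the P granule helicase gene glh-1 (1.41, SE 0.14), the synaptonemal complex gene syp-1 (1.30, SE 0.18) and mes-3 (0.96, SE 0.07). Cell death genes rose in 9 of 16 and fell in 3, and 11 rose when adjusted over the list alone (adjusted p = 0.0383, adjusted p = 0.697 with an estimated correlation), with egl-1 (2.83-fold, log2 SE 0.15) and the caspase gene ced-3 (0.69, SE 0.11) among the rises and the X-linked nuclease gene nuc-1 (-0.86, SE 0.10) among the falls. In wild-type embryos these lists differed by date too: at code 2 against code 4 the medians were -0.48 for cell division, -0.54 for RNA interference, -0.58 for germline and -0.33 for cell death genes.

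Epidermal and cuticle genes fell in XO embryos, 19 of 33 with 3 risen, and 22 fell and 4 rose when adjusted over the list alone (adjusted p = 6.53e-05, adjusted p = 0.246 with an estimated correlation). They include the moulting gene mlt-10 (-1.08, SE 0.17) and the collagen genes sqt-2 (-0.97, SE 0.13) and dpy-2 (-0.76, SE 0.09). Ribosomal protein genes fell in 45 of 75 and rose in 2, and 50 fell when adjusted over the list alone (adjusted p = 5.64e-12, adjusted p = 0.290 with an estimated correlation), with the X-linked rpl-23A.1 (-0.63, SE 0.05) and with rps-27A (-0.56, SE 0.08), while rpl-41.1 rose (0.37, SE 0.05). Within date code 2, where the list was called too, 19 of the 75 fell and 2 rose (adjusted p = 6.68e-05, adjusted p = 0.472 with an estimated correlation). Heat-shock genes fell in 8 of 18 and rose in 2, the same counts over the list alone (adjusted p = 0.0255, adjusted p = 0.246 with an estimated correlation), with hsp-16.2 (-1.55, SE 0.39), hsp-60 (-1.47, SE 0.15), the X-linked hsp-3 (-1.33, SE 0.16) and hsp-1 (-0.97, SE 0.12). Oxidative phosphorylation genes fell in 7 of 27 and rose in 2, the same counts over the list alone (adjusted p = 0.0356, adjusted p = 0.850 with an estimated correlation). The X-linked asg-2 (-0.93, SE 0.12), sdha-1 (-0.82, SE 0.10) and gas-1 (-0.77, SE 0.10) fell and isp-1 rose (0.24, SE 0.04). Within date code 2 the call of the list was lost, with 8 risen, 4 fallen and a median of 0.131 (camera adjusted p = 0.535).

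The remaining lists were not called by camera in XO embryos (adjusted p from 0.123 to 0.988). Of these, fry called dosage compensation genes, sdc-2 included, downward (fry adjusted p = 6.76e-05) and detoxification genes upward (0.0294). Dosage compensation genes rose in 4 of 10, with capg-1 (0.49) and dpy-28 (0.44), and fell in 2, the X-linked sdc-2 and sdc-1 (-1.25). In the limma fit to the shared date code alone the call of dpy-28 was lost (adjusted p = 0.0781). Sex determination genes rose in 5 of 18, with fog-2 (0.95) and tra-3 (0.46), and fell in 5. Muscle genes rose in 4 of 32 and fell in 12, with unc-95 (-1.17), neuronal genes rose in 2 of 34 and fell in 6, with the X-linked tubulin gene mec-7 (-0.96), and intestinal genes rose in 1 of 16 and fell in 5. Fatty acid genes rose in 10 of 26, with the desaturase gene fat-3 (1.52), and fell in 8, with ech-6 (-1.34). Chromatin genes rose in 10 of 22 and fell in 4, detoxification genes rose in 4 of 23 and fell in 2, early maternal messages rose in 3 of 26 and fell in 1, and early zygotic regulators rose in 3 of 21 and fell in 6. In the sperm list 1 of 20 rose and 1 fell, 2 of 13 pharyngeal genes fell and 1 of 26 immunity genes fell. Of 8 yolk and adult genes 0 passed in limma, and 0 had an unadjusted p under 0.05. Adjusted over the list alone, 11 fatty acid, 3 detoxification and 2 maternal genes rose and 5 chromatin genes fell, the pharyngeal and immunity falls were not called, and the other counts of uncalled lists stayed as given.

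In XO embryos 5109 genes changed in all, 2698 up and 2411 down, against 2170 up and 2630 down with each array re-centred on its autosomal median. Within the shared date code 7683 genes changed, and 8039 changed with array weights, 3329 at an adjusted p under 0.01 and 1704 with at least 1.5-fold change. In the fit by group and date code, within date code 2, cell division genes rose in 36 of 36 (adjusted p = 0.0412 with an estimated correlation), RNA interference genes in 22 of 25 (adjusted p = 0.0423 with an estimated correlation) and germline genes in 17 of 24 (adjusted p = 0.134 with an estimated correlation). Muscle genes fell there in 22 of 32, neuronal genes in 23 of 34, pharyngeal genes in 11 of 13 and intestinal genes in 10 of 16 (adjusted p = 0.216, 0.216, 0.145 and 0.216 with an estimated correlation), and chromatin genes rose in 14 of 22 (adjusted p = 0.129 with an estimated correlation). At the preset correlation camera called these 5 lists there (adjusted p = 1.45e-08, 3.9e-07, 6.68e-05, 6.85e-05 and 1.94e-05), though not in the joint fit.

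Wild-type embryos of the 2 date codes on egg plates differed along the same tissue lists. The wild-type arrays of date code 2 enter this contrast and the XO comparison within date code 2, with opposite sign. Opposite changes of the lists in these contrasts are therefore partly built in. At date code 2, muscle genes were higher in 24 of 32, neuronal genes in 25 of 34, pharyngeal genes in 8 of 13 and intestinal genes in 10 of 16, with medians of 0.67, 0.65, 0.66 and 0.62. Cell division genes were lower in 31 of 36, RNA interference genes in 22 of 25, germline genes in 17 of 24, early maternal messages in 17 of 26 and early zygotic regulators in 14 of 21, with medians of -0.48, -0.54, -0.58, -0.47 and -0.58. With an estimated correlation the adjusted p of these lists ran from 0.0808 to 0.278. In all 6855 genes differed (3 against 3 arrays), with large rises in dbd-13 (3.81, SE 0.26), cpi-1 (3.55, SE 0.17), hrg-7 (3.01, SE 0.48) and ttr-17 (2.83, SE 0.20), and large falls in dhs-8 (-2.42, SE 0.27) and the carotenoid oxygenase gene bcmo-1 (-1.51, SE 0.17). The X shift between these date codes was 0.276.

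Among XO embryos 6934 genes differed between date codes 2 and 5 (3 against 5 arrays). Those of code 2 had higher mcd-1 (2.01, SE 0.10), atg-9 (1.96, SE 0.19), lido-9 (1.85, SE 0.10) and xrn-2 (1.82, SE 0.13), and lower dbd-13 (-2.40, SE 0.23) and tent-5 (-2.27, SE 0.30). Oxidative phosphorylation genes were higher in 16 of 27 (adjusted p = 0.0215 with an estimated correlation). The X shift between these codes was -0.211. With at least 1.5-fold change, 2949 genes differed between the wild-type dates and 2373 between the XO dates, beside 1704 for XO, 2280 for sdc-2 and 3425 for dpy-27 embryos against their controls.

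The effects of sdc-2 and dpy-27 in XX embryos differed from the XO effect foremost on X. The X shift was higher by 1.06 in sdc-2 (SE 0.10) and by 1.03 in dpy-27 embryos (SE 0.10), each with an exact permutation p of 5e-05 over 60060 relabellings within the comparisons, which assume no shift in either. Those relabellings also treat the egg-plate arrays as independent, although arrays of a date code lay together, so this p can overstate the evidence. Over all genes the differences in X shift were 0.465 and 0.427. Relative to the XO effect, 919 X-linked genes were higher and 1 lower in sdc-2 embryos, and 1051 higher and 13 lower in dpy-27 embryos. Over all chromosomes 2834 genes differed for sdc-2 (1163 higher, 1671 lower) and 3644 for dpy-27 (1860 higher, 1784 lower). After joint quantile normalisation 1388 were higher and 1496 lower for sdc-2, and 1633 higher and 1594 lower for dpy-27. Re-centring on autosomal medians gave 1510 higher and 929 lower for sdc-2, and 2852 higher and 1092 lower for dpy-27, where it moves the median of all genes by 0.138. Among autosomal genes the difference for her-1 was 3.36 in sdc-2 (SE 0.13) and 0.83 in dpy-27 embryos (SE 0.13). This gene is mutated in the XO strain, where it fell by 0.69, and its change in dpy-27 embryos was 0.14. The differences therefore include the strain's own fall.

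The function fry called 26 of the 66 list tests, and camera at the preset correlation 19. Of the camera calls, fry missed oxidative phosphorylation genes in XO (fry adjusted p = 0.0537) and early maternal messages in sdc-2 embryos (0.0936). Where lists were not called by camera, their median, mean and test sometimes differed in sign. In XO embryos this held for dosage compensation genes (median 0.16, mean -0.46, fry downward), sex determination genes, early maternal messages, neuronal genes, yolk and adult genes and sperm genes. In sdc-2 embryos it held for pharyngeal, neuronal and fatty acid genes, and in dpy-27 embryos for muscle, pharyngeal and chromatin genes. The lists called by camera kept the direction of their median under re-centring and quantile normalisation. Of the uncalled ones, sex determination genes in XO embryos, neuronal, yolk and cell division genes in sdc-2 embryos, and pharyngeal, sperm, cell division, chromatin and immunity genes in dpy-27 embryos changed sign.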

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

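The tests of the wild-type date difference against the X shift and against the heat-shock genes, and that of the shift between the wild-type date codes, were chosen only after the result was seen.

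Expressed X-linked genes stood 0.67 above autosomal genes in sdc-2 and 0.63 above them in dpy-27 XX embryos, each in 3 of 3 arrays. Brightness of the X-linked probes is argued against, since the shift was 0.670 and 0.635 against autosomal genes of the same brightness. A difference of the kind seen between the wild-type date codes, whether or not it is one of embryo age, predicted shifts of 0.012 and -0.002 from the autosomal genes. The autosomal slopes behind them were 0.044 and -0.006, so both had to be small. They cannot speak to a date difference that acts on X. Over expressed X-linked genes the effects correlated with the wild-type date difference at 0.253 (sdc-2) and 0.121 (dpy-27), against 0.052 and -0.005 on autosomes. Embryo age itself was not measured, and another difference between collections cannot be told apart from genotype, because mutant and control differ in date code within each comparison, and the wild-type date codes alone differed by 0.276. Loss of the complex, which the design names, stays open as the biological explanation beside it.

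Autosomal effects of sdc-2 and dpy-27 correlated at 0.530 over expressed genes, although the comparisons share no arrays. With the difference between the wild-type date codes regressed out the correlation was 0.531, with gene length 0.517, with brightness 0.532, and with all 3 together 0.518. None of these accounts for the correlation. A response of autosomal genes to loss of the complex, and another difference between wild-type and mutant collections, both stay open, and the XO effect correlated with them at 0.501 and 0.504 on autosomes. The XO comparison shares date code 5 with the sdc-2 arrays and date code 2 with the NG controls.

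Heat-shock genes fell in dpy-27 embryos, 10 of 18 with a median of -1.505 over those 10. A raised level peculiar to the NG control collection is argued against: after joint quantile normalisation hsp-16.2, hsp-16.41 and hsp-70 had a median of -0.383, and the 10 genes one of -0.248, in these controls relative to egg-plate controls of the same date code. The difference between the wild-type date codes predicted a median of -0.002 through its slope over autosomal genes. That slope was -0.006, so the prediction had to be small whatever the heat-shock genes did, and it decides nothing about them. Taken directly, hsp-70 was higher at code 2 than at code 4 by 2.06, hsp-16.2 and hsp-12.3 by 1.30, hsp-16.41 by 0.96 and hsp-60 by 0.59. The genes crt-1 (-0.29), dnj-12 (-0.27) and hsp-4 (-0.33) went the other way. A raised level in wild-type collections of date code 2 stays open for part of the list: on egg plates hsp-16.2 averaged 12.29 at code 2 and 11.04 at code 4, but hsp-1 and hsp-90 differed by 0.02 and -0.06 between these codes, and XO embryos had less hsp-16.2 at code 2 (9.41) than at code 5 (10.45). The value in dpy-27 embryos was 7.56, below both, and the dpy-27 genotype, which the design names, stays open as well.

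The 6 arrays of the sdc-2 comparison allow 10 splits, as do the 6 of dpy-27 and the 6 of the wild-type dates, too few for a share under 0.05. In each of these, 1 of the 10 splits, the real one, gave as many genes (3390, 5228 and 6855), and the highest other split gave 0. For the XO comparison 2 of 100 drawn splits gave as many as the real 5109, so chance is excluded as the sole source at that share. The highest other drawn split gave 5253 and put the 5 XO arrays of date code 5 and 1 of code 2 against the other 8 arrays. It thus follows a date code as well as genotype, and the median of the other drawn splits was 0. A split by date alone, codes 4 and 5 against code 2, gave 2075, and within code 2 the genotypes differed in 7118 genes in the fit by group and date.

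For the XO date codes chance is excluded (6934 genes, 1 of 56 splits, highest other 1912). Differences between effects were regrouped within each comparison, which removes the effects themselves, so these counts do not test whether 2 effects are equal. As many genes came in 3 of 100 regroupings for sdc-2 against dpy-27 (1526 genes, highest other 2652), 1 of 100 for sdc-2 against XO (2834 genes, highest other 1334) and 1 of 100 for dpy-27 against XO (3644 genes, highest other 2848).

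The differences between effects were each tested in limma, the X shifts by a permutation that assumes no shift in either comparison. Between sdc-2 and dpy-27 embryos the effects differed by -1.55 for sdc-2 transcripts, 2.53 for her-1, 4.83 for cnc-4, 4.08 for hsp-16.2, 4.06 for hsp-16.41, 3.31 for col-48 (call lost without either of a pair of arrays), -2.06 for rhgf-3, -1.92 for nhr-163 and -1.91 for pptr-1. Between sdc-2 and XO embryos they differed by 1.061 in the X shift, 4.74 for sdc-2, 3.36 for her-1, 4.54 for xol-1, 2.55 for unc-9, 3.24 for cpi-1, 3.00 for cnc-4, -3.08 for fmo-2, -2.64 for srlf-24, -2.63 for gpdh-1 and -2.50 for ugt-31, whose call was lost without any 1 of 4 arrays. Between dpy-27 and XO embryos they differed by 1.026 in the X shift, 6.28 for sdc-2, 0.83 for her-1, 3.83 for xol-1, 2.59 for unc-9, 2.25 for ctbp-1, -3.64 for col-48, -2.86 for hsp-16.2, -2.63 for hsp-16.41 and -2.53 for col-77. The XO levels of sdc-2 and xol-1 are at background, so the differences given for these genes against XO embryos are limited by it. The genes sdc-2, her-1, xol-1 and unc-9 are mutated in the XO strain. Their differences against XO embryos therefore include the strain's own changes in them.

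A single array stood apart from the rest of its group in 3 of 118 sets of values tested, where chance gives about 5.9. These were srd-48 in XO_TY2222 replicate 4 (5.38, others 5.05 to 5.19), tra-3 in WT_XX_egg replicate 1 (10.18, others 10.38 to 10.5) and rpl-23A.1 in WT_XX_egg replicate 5 (13.17, others 13.07 to 13.1).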

How the results depend on the processing

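Alternatives for the date differences, for the lists in XO embryos and some of those for differences between effects and correlations were chosen after seeing the data. Where a result below moved, the cause was not tested, except that stricter thresholds and fewer arrays or genes are smaller tests by construction. At an adjusted p under 0.01 the counts were 3438 (dpy-27), 1859 (sdc-2) and 3329 (XO), and 341 X-linked genes rose in both XX mutants. With at least 1.5-fold change they were 3425 (dpy-27), 1704 (XO), 2949 (wild-type dates) and 2373 (XO dates). Array weights gave 5588 (sdc-2) and 8039 (XO). With the date code as a random block, where arrays of a date correlated at 0.619, 1063 genes changed in dpy-27, 43 in sdc-2 and 5830 in XO embryos. Within the shared date code the XO comparison gave 7683 genes and an X shift of -0.676 (exact permutation p = 0.1, the smallest 3 against 3 allows), and dpy-27 rose by 0.286, as it did with the date code as a fixed block and with the replicate letter as a block, while the median of oxidative phosphorylation genes was 0.131 in both date settings, where the list was not called. The fixed block takes the genotype effect from date code 2 alone, since codes 4 and 5 each hold a single egg-plate group. These settings therefore had to give the same changes and are not separate checks. In the dpy-27 and XO comparisons no letter clearly paired the arrays by correlation. In sdc-2, arrays of the same letter correlated above the highest other letter for B (0.377 against 0.022) and C (0.287 against -0.133). For A they did not (0.084 against 0.283). Letters as a block gave 4952 (sdc-2), 6553 (dpy-27) and 7475 (XO, shared date). The X shift over all genes was 0.257 (dpy-27), 0.295 (sdc-2) and -0.17 (XO), with differences from XO of 0.427 and 0.465, and over the brightest genes 0.719 (dpy-27) and 0.789 (sdc-2). With an estimated correlation 2 lists were called in place of 19, and 21 were with the mean of probe sets. Without probe sets ending in _s_at or _x_at, ajm-1 (-0.154), oma-2 (0.304) and sqt-3 (0.203) turned direction in dpy-27 embryos. Leaving out 1 array gave 2089 (without sdc2_XX replicate B) to 3136 genes for sdc-2, with 2203 without WT_XX_RNAi replicate C, 4195 to 4467 for dpy-27, 4467 to 5433 for XO, 993 (without dpy27_XX replicate C) to 1449 for sdc-2 against dpy-27, with 1010 without WT_XX_RNAi replicate B, 1983 to 3169 for sdc-2 against XO, 2859 to 3812 for dpy-27 against XO, 5713 to 6599 for the wild-type dates and 5632 to 6872 for the XO dates. X shifts kept their sign with any 1 array left out, at 0.626 to 0.706 (sdc-2), 0.597 to 0.672 (dpy-27) and -0.429 to -0.358 (XO). Of 231 values of named genes, 147 kept call and direction in all settings, 79 lost the call in at least 1, 4 turned direction and 2 gained a call. The planned test of NG against egg plates over all genes was not run. Signal over background limits the dim genes, for which over all genes the X shift was smaller.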

Other observations

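The split of X-linked genes by their response, and the hypothesis on X-linked responses, were tests chosen only after the result was seen.

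Of the 8 genes of the mitochondrial genome, 6 rose in XO embryos, 2 in sdc-2 embryos and 8 in dpy-27 embryos, with median log2 changes of 0.22, 0.22 and 0.51. They were not tested as a list.

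X-linked genes were split by whether they rose in the XX mutants. Of the 529 that rose in both sdc-2 and dpy-27 embryos, 138 fell and 26 rose in XO embryos, with a median of -0.06. Of the 474 expressed X-linked genes that rose in neither mutant, 316 fell and 2 rose, with a median of -0.58. The set that rose in both was not limited to expressed genes, so dim genes could enter only that set. The XO comparison shares no arrays with the other comparisons but does share date codes with them. Code 5 holds XO and sdc-2 arrays, and code 2 holds egg-plate and NG controls. A date difference could therefore enter both sides, and the difference between the sets was not tested.

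A hypothesis is that X-linked genes which rise more on loss of the complex in XX embryos may fall less in XO embryos, and more so than the same relation on autosomes. The test compared the correlation with the XO effect over X-linked genes with that over autosomal genes. The wild-type date difference, gene length and brightness were regressed out of both effects. For sdc-2 these adjusted correlations were 0.583 and 0.501, a difference of 0.083. For dpy-27 they were 0.557 and 0.499, a difference of 0.058. Without adjustment they were 0.615 and 0.501 for sdc-2, and 0.551 and 0.504 for dpy-27. With 1 array left out, unadjusted sdc-2 values ran from 0.585 to 0.646 on X and 0.466 to 0.541 on autosomes, without overlap. For dpy-27 they ran from 0.528 to 0.583 and from 0.469 to 0.545, which overlap. Such ranges are not intervals of uncertainty, so neither case tells the correlations on X and on autosomes apart. The adjusted differences fell short of the margin set for the test. It therefore does not tell the relation on X apart from the one on autosomes.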
